A study of Homo sapiens with 16 samples.

How the data were processed

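Total RNA of 16 samples of MCF10A, a non-tumorigenic human breast epithelial cell line, was labelled with Cy3 and measured on Agilent 1-colour oligonucleotide arrays, 1 array per sample. Each array held 45015 spots, of which 43376 were not controls and carried 41000 probes of 60 bases; 264 probes were spotted more than once. The deposited files are Feature Extraction outputs, and per the file headers the values used here are processed intensity, that is, background-subtracted and spatially corrected Cy3 intensity on a linear scale, scanned at 5 micron, with saturation at 65528. The authors did not scale the arrays to each other, and the deposited series values equalled the processed intensity in the files on all 16 arrays. The authors named Feature Extraction 9.5.3.1 in their notes, while the file headers name version 10.5.1.1. The arrays lay on 4 slides of 4, scanned separately; slides 1 and 2 held vehicle and sulforaphane arrays and slides 3 and 4 held the siRNA arrays, with 2 treated and 2 control arrays on each slide. Per the labels, treated cells grew in heavy isotope medium and their controls in light medium in both experiments, so the medium cannot be told apart from the treatment within an experiment. The labels describe the treatment as lasting 24 h, and elsewhere place both the start of sulforaphane and the harvest at 24 h after plating, so the exposure time rests on the sample descriptions.

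Processed intensities were put on the log2 scale and the 75th percentile of each array's non-control spots was subtracted. Spots marked as non-uniform or as population outliers by Feature Extraction were treated as missing (52 to 123 per array), and repeated spots of a probe were averaged. A probe was kept where Feature Extraction called it well above background, by a multiplier of 13, on all arrays of at least 1 group, which left 24508 probes. Gene names came from the array design and were matched to the reference table by RefSeq accession (26386 probes), by symbol (2399) or by synonym (596), and 11619 probes had no match. For each gene name the probe with the highest mean over the 16 arrays was used, without regard to group; 5131 tested genes had several probes. Of 29846 gene names, 17530 were tested, of which 12030 were gene symbols and 5500 were placeholders such as clone or accession names. An hg19 position was given for 40595 probes; no genome sequence was at hand, so probes were not aligned again.

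A linear model of the 4 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with 12 residual degrees of freedom, and 4 contrasts were taken from it: sulforaphane minus vehicle, KEAP1 siRNA minus non-targeting (NTC) siRNA, the difference between these responses, and NTC siRNA minus vehicle. P values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, tests were two-sided, and a gene was said to change at an adjusted p under 0.05. Changes are log2 differences of group means with their standard error (SE) from limma, and 4 arrays per group limit their precision; the median SE was 0.081, and 0.114 for the difference. Levels of KEAP1 and NFE2L2 were also compared by exact permutation tests, whose smallest possible two-sided p with 4 against 4 arrays is 0.0286. No covariate was used; the slide was fitted as a block in an alternative, and no slide held both control groups, so there the slide could enter only as a random effect, with a consensus correlation of 0.029. Where a probe was not well above background in any array of a group, or was saturated in a group, its fold change is given as "at least" a value computed from the lowest intensity called well above background on each array of that group, or from the saturated value, since the fitted fold is then no bound; where both groups were below background no fold is given. The p value beside such a bound is that of the fitted change, and the bound itself was not tested. Among tested genes 1127 were dim in a group and 96 were saturated in a group.

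The contrasts, tests, named-gene rule, gene lists and most alternatives were chosen before the data were examined. The 26 gene lists were glutathione, thioredoxin, quinone and carbonyl metabolism, heme and iron, NADPH and pentose phosphate, ABC efflux transporters, proteasome, heat shock, ATF4 and amino acid, unfolded protein response, mitosis, DNA replication, p53 targets, NF-kB and cytokines, interferon response, metallothionein, cholesterol synthesis, fatty acid synthesis, AhR (aryl hydrocarbon receptor) battery, immediate early, histones, basal epithelial, luminal epithelial, keratinocyte differentiation, mesenchymal, and blood and endothelial. They were written from general knowledge, not from these samples; NQO1, ALDH3A1 and UGT1A6 stand in both the quinone and the AhR lists. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, and again with a correlation estimated from the residuals, with adjustment over the 26 lists of a contrast. The fry test, which asks whether the genes of a list move on balance one way without comparing them with other genes, was run as an alternative.

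Genes were named by rule: KEAP1 and NFE2L2 always, and for each main comparison the 10 largest rises and 10 largest falls with an adjusted p under 0.05, no overlap between the 4 treated and the 4 control arrays, and a symbol that is not a placeholder. The 5 largest in each direction were named for the difference of the responses and for the controls, as were the 5 per direction called the same way in both responses with the largest smaller change. For each list up to 4 members with the largest passing change could be named, or the 2 with the smallest p where fewer than 2 passed. A few genes that the rule names are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

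Alternatives covered normexp background correction (offset 50) with quantile scaling, quantile scaling, median centring, no filter on dim probes, probes well above background on all 16 arrays, outlier-marked spots kept, the mean or the lowest probe of a gene, an intensity trend with robust variance, array weights, each experiment's own 8 arrays, the deposited series values, a replicate block, a slide block, thresholds of 1.5-fold, 2-fold and an adjusted p under 0.01, and leaving out each array. An alternative with named genes only was added after seeing the data. The scan day was the same for all arrays and each slide had its own scan, so a scan block was not run.

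The fit was tested on simulated data built from the residual spread: changes of 0.5, 1 and 2 log2 units were recovered for 74.6%, 83.6% and 100% of genes in the sulforaphane comparison and for 70.1%, 91% and 98.5% in the knockdown comparison. For the difference of the responses recovery was 61.2%, 85.1% and 97%. Of 16683 unchanged genes, 7, 5, 16 and 0 were called in the sulforaphane, knockdown, difference and control contrasts. The simulated list shifted by 0.5 in each experiment was called and 0 other lists were. The simulated noise was independent between genes, whereas the correlation estimated within a real list reached 0.253 for mitosis and 0.347 for metallothionein. The list result therefore does not give the rate of false list calls on the real arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with version 1.17.8 of data.table in R, for reading, counting and drawing. Proteomic data mentioned in the series title are not among the deposited array files and were left out, as were spike-in and other control spots.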

Results

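RNA levels were measured in MCF10A, an immortalised, non-tumorigenic human breast epithelial cell line, on 16 single-colour Agilent arrays with 1 array per sample. The samples formed 4 groups of 4 biological replicates: acetonitrile vehicle, 15 µM sulforaphane, 30 nM non-targeting control (NTC) siRNA and 30 nM KEAP1 siRNA, all described as 24 h exposures. Sulforaphane is an isothiocyanate from cruciferous plants that modifies cysteines of KEAP1, and KEAP1 is the adaptor protein that directs the transcription factor NRF2, encoded by NFE2L2, to degradation. Each array carried 43376 non-control spots. The 75th percentile of processed intensity ran from 259.4 to 329.5 with vehicle, 291.7 to 366.4 with sulforaphane, 201.9 to 267.5 with NTC siRNA and 234.7 to 286.3 with KEAP1 siRNA. Between 54.2% and 62.7% of spots per array were well above background, and 81 to 158 spots per array were saturated. Replicates of a group correlated across probes with r of 0.9922 to 0.996. After filtering, 17530 genes were tested with limma. Changes below are log2 differences ± SE with n = 4 arrays per group unless stated otherwise, and the number of arrays limits their precision.

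The first comparison asked which transcripts differ after sulforaphane. The largest rise of a gene with a symbol was that of AKR1B10 (probe at chromosome 7, 134225799 to 134225858, hg19), an aldo-keto reductase that reduces reactive aldehydes: it was 306-fold higher (8.26 ± 0.13, adjusted p = 3.96e-15, limma). AKR1C1, another aldo-keto reductase, rose by 4.91 ± 0.08, and CYP4F12, a cytochrome P450 fatty acid hydroxylase, by 4.87 ± 0.17. All 29 measured DNA replication genes and all 26 mitosis genes fell, among them POLA1 (-2.11 ± 0.05), the catalytic subunit of the polymerase that starts DNA synthesis. MYB, a transcription factor of proliferating progenitor cells, was at least 30.1-fold lower (adjusted p = 4.76e-14, limma). Of the 17530 genes, 11175 (63.7%) changed at an adjusted p under 0.05 in limma, 5251 up and 5924 down, and 2003 changed at least 2-fold, 1111 up and 892 down. The 4 sulforaphane arrays did not overlap the 4 vehicle arrays for 10629 genes (60.6%), where chance gives 2.9%.

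CYP4F12 was well above background on 1 of 4 vehicle arrays. Several of the largest rises were of genes that were not well above background in vehicle. Their folds are lower bounds, set against the lowest intensity called well above background on each array. The p values given with bounds, here and below, test the fitted change and not the bound. ANXA10, a membrane-binding annexin, was at least 29.1-fold higher (adjusted p = 8.43e-12, limma), CYP4F11 at least 20.1-fold (4.97e-09), and SPANXA1, a cancer-testis gene of sperm nuclei, at least 18.1-fold (5.48e-09). SMOC2, a matricellular protein, was at least 9.93-fold higher (1.88e-10), F2RL2, a protease-activated receptor, at least 8.49-fold (9.36e-13), and SPANXD at least 6.33-fold (9.64e-11). Among the largest falls, TNFRSF6B, a decoy receptor for FAS ligand, dropped by 3.88 ± 0.08, CAMK2B, a calcium/calmodulin-dependent kinase, fell by 4.95 ± 0.27, and SLITRK6, a neuronal transmembrane protein, fell by 3.22 ± 0.17. ANKRD22 was at least 11.6-fold lower (1.43e-10), CA9, a hypoxia-induced carbonic anhydrase, at least 5.30-fold (1.42e-06), and E2F8, an atypical E2F cell cycle regulator, at least 4.87-fold (2.01e-10). RGMA, a repulsive guidance molecule, was at least 2.60-fold lower (2.37e-06), FZD10, a Wnt receptor, at least 2.46-fold (2.56e-09), and NRTN, the growth factor neurturin, at least 1.84-fold (3.18e-08).

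KEAP1 mRNA itself (probe at chromosome 19, 10597262 to 10597321, hg19) was 1.27-fold higher with sulforaphane (0.34 ± 0.06, adjusted p = 0.000118, limma). NFE2L2 mRNA (chromosome 2, 178095277 to 178095336) differed by 0.03 ± 0.11 (adjusted p = 0.831, limma; exact permutation p = 0.771). The sign of that NFE2L2 value turned with array weights (-0.01) and without sulforaphane array 3 (-0.03) or 4 (-0.02).

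**Figure D1:**
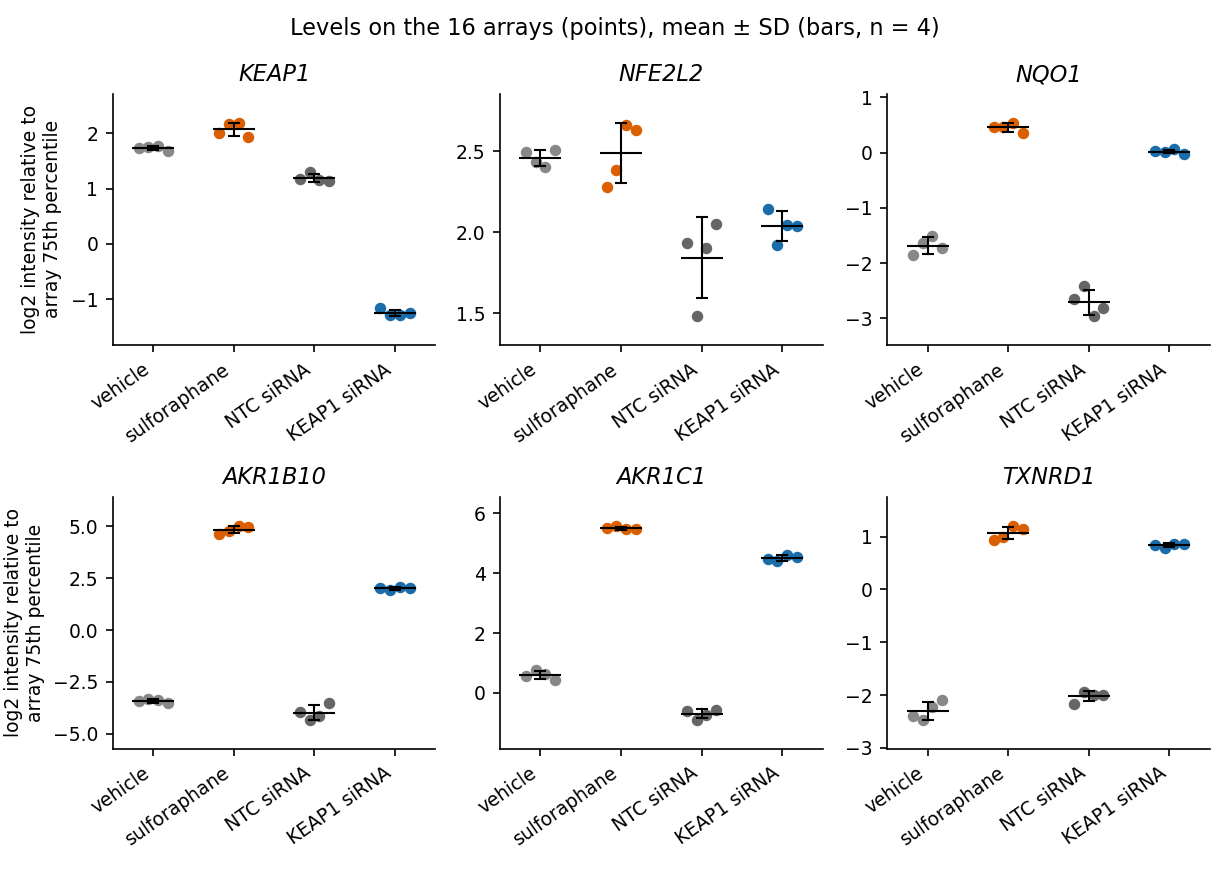
Scaled log2 intensity of KEAP1, NFE2L2, NQO1, AKR1B10, AKR1C1 and TXNRD1 in the 4 groups; points are arrays, and bars are the mean ± SD of 4 arrays. KEAP1 averages -1.25 with KEAP1 siRNA against 1.20 with NTC siRNA, and AKR1B10 averages 4.84 with sulforaphane against -3.41 with vehicle.

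Gene lists of redox and detoxification functions rose with sulforaphane against the other genes (camera). In the quinone and carbonyl metabolism list 15 of 17 genes rose and 2 fell (adjusted p = 1.41e-07, camera), with AKR1C3 up by 4.77 ± 0.07 and UGT1A6, a glucuronosyltransferase, up by 4.74 ± 0.06. In the heme and iron list 11 of 13 rose and 2 fell (6.22e-05), including ferritin light chain FTL at 3.72 ± 0.05 and heme oxygenase HMOX1 at 3.29 ± 0.12. In the glutathione list 13 of 21 rose and 5 fell (0.00341), including the cystine transporter SLC7A11 at 3.49 ± 0.10 and GCLC, a subunit of the enzyme that limits glutathione synthesis, at 2.15 ± 0.10. Among p53 targets 16 of 19 rose and 1 fell (2.92e-06), with the cell cycle inhibitor CDKN1A at 2.86 ± 0.08 and TP53INP1 at 1.80. These 4 calls held with an estimated correlation (adjusted p = 0.0109, 0.0109, 0.0334 and 0.0109). The thioredoxin list was not called (adjusted p = 0.117), with 6 of 13 up and 4 down, although thioredoxin reductase TXNRD1 rose by 3.37 ± 0.08 and sulfiredoxin SRXN1 by 2.59 ± 0.07.

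DNA replication genes fell as a list (29 of 29, adjusted p = 7.49e-14, camera; adjusted p = 0.0109 with an estimated correlation). POLE2, a subunit of the leading-strand polymerase, fell by 2.10 ± 0.08, CDC45, part of the replicative helicase, fell by 1.93 ± 0.06, and CCNE2, cyclin E2, was at least 3.14-fold lower (adjusted p = 3.76e-08, limma). Mitosis genes fell in 26 of 26 cases (adjusted p = 6.16e-11, camera; adjusted p = 0.06 with an estimated correlation), with the proliferation marker MKI67 at -1.78 ± 0.11 and the kinase AURKB at -1.71 ± 0.09. Of 23 ATF4 and amino acid genes 16 fell and 3 rose (0.00194; adjusted p = 0.159 with an estimated correlation), with CHAC1, which degrades glutathione, at -1.89 ± 0.11 and ALDH1L2 at -1.59. Metallothionein genes fell in 8 of 12 cases, 1 rising (0.0223; adjusted p = 0.348 with an estimated correlation). MT1E, MT1H and MT1L were saturated with vehicle and at least 3.12-fold, 2.48-fold and 2.25-fold lower with sulforaphane (adjusted p = 5.65e-10, 1e-08 and 7.56e-09, limma). In the fatty acid synthesis list 9 of 12 fell and 1 rose (0.0161; adjusted p = 0.0784 with an estimated correlation), including the lipogenic regulator SREBF1 at -1.57 and the desaturase SCD at -0.80.

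Interferon response genes rose in 16 of 24 cases and 4 fell (adjusted p = 0.000377, camera; adjusted p = 0.06 with an estimated correlation), IFIT2 by 1.33 and IFIT3 by 1.25. AhR battery genes rose in 5 of 7 cases and 0 fell (0.00569; adjusted p = 0.0675 with an estimated correlation), CYP1A1 by 2.42 and NQO1, a quinone reductase that the quinone list also holds, by 2.14. Of 17 NF-kB and cytokine genes 10 rose and 4 fell (0.0223; adjusted p = 0.203 with an estimated correlation), IL1A by 1.89 and NFKB2 by 1.44. ABC efflux transporters rose in 5 of 8 cases and 1 fell (0.0229; adjusted p = 0.0675 with an estimated correlation), with ABCC2 at 2.41 and ABCG2 at -0.90.

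The other lists were not called with sulforaphane. Counts up and down were 12 and 5 of 21 for immediate early genes (adjusted p = 0.055, camera), 8 and 3 of 14 for basal epithelial genes (0.055) and 3 and 11 of 17 for histones (0.0587). They were 10 and 8 of 20 for heat shock genes, where the small heat shock proteins CRYAB and HSPB8 rose by 3.20 and 3.05 (0.222), and 6 and 2 of 13 for luminal epithelial genes (0.328). They were 6 and 13 of 23 for cholesterol synthesis (0.443), 7 and 4 of 18 for keratinocyte differentiation (0.544), 6 and 6 of 14 for NADPH and pentose phosphate (0.699), 10 and 10 of 31 for proteasome (0.718) and 7 and 7 of 19 for the unfolded protein response (0.718). They were 4 and 4 of 13 for mesenchymal genes (0.724) and 1 and 2 of 6 for blood and endothelial markers (0.824), where the receptor CSF1R rose by 2.57. The last pair had medians of -0.07 and -0.01 with means of 0.08 and 0.07 and a test sign of up. Adjusted over the list alone, counts were the same except for interferon response (18 up) and metallothionein (9 down).

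Within slides 1 and 2, with 2 arrays per group, 8949 and 9739 genes changed (limma), and the changes on both slides correlated at r = 0.93 across genes, which are not independent replicates. With the slide as a block 11225 genes changed.

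The second comparison asked which transcripts differ when KEAP1 is knocked down. KEAP1 mRNA fell to 18.4% of the NTC level (-2.44 ± 0.06, adjusted p = 5.38e-13, limma; exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give). It fell by 1.71 with normexp background and quantile scaling. Among genes with a symbol, the largest rises again included aldo-keto reductases: AKR1B10 was 63.5-fold higher (5.99 ± 0.13), AKR1C1 rose by 5.21 ± 0.08 and AKR1C3 by 3.99 ± 0.07. The aldehyde dehydrogenase ALDH3A1 rose by 4.71 ± 0.29. For AKR1C1, the dimmest of 3 other probes gave 0.17 (adjusted p = 0.711, limma; 2.41e-19 to 0.711 over the alternatives). AKR1B10 and GPAT3 were well above background on 2 of 4 NTC arrays, and CYP4F12 on 1 of 4. UGT1A6 rose by 3.70 ± 0.06, the lipid synthesis enzyme GPAT3 by 3.38 ± 0.27, OSGIN1, an oxidative stress-induced growth inhibitor, by 3.29 ± 0.10 and CYP4F12 by 3.25 ± 0.17. Of 17530 genes 6160 (35.1%) changed in limma, 3635 up and 2525 down, and 476 changed at least 2-fold, 217 up and 259 down. With median centring of the arrays the excess of rises was absent, with 2733 up and 2755 down. The groups did not overlap for 6153 genes (35.1%), where chance gives 2.9%.

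Among the genes that were not well above background with NTC siRNA, CYP4F11 was at least 8.22-fold higher (adjusted p = 6.76e-07, limma) and ANXA10 at least 2.44-fold (2.57e-08). FGFRL1, a decoy-like fibroblast growth factor receptor, fell by 2.95 ± 0.07, LYPLA1, a protein depalmitoylating thioesterase, fell by 2.66 ± 0.07, and SFT2D1, a vesicle transport protein, fell by 2.46 ± 0.08. VPS25, a subunit of the ESCRT-II sorting complex, fell by 2.42 ± 0.06, PDPN, the mucin-like glycoprotein podoplanin, fell by 2.33 ± 0.06, and RWDD4 fell by 2.29 ± 0.06. CXCL14, a chemokine of epithelia, was at least 5.10-fold lower (7.8e-08), and SCNN1G, an epithelial sodium channel subunit, at least 1.91-fold (5.49e-09). NFE2L2 mRNA differed by 0.20 ± 0.11 (adjusted p = 0.199, limma; exact permutation p = 0.2).

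Redox lists rose with KEAP1 siRNA. In the quinone and carbonyl metabolism list 14 of 17 rose and 1 fell (adjusted p = 4.09e-15, camera), and in the glutathione list 14 of 21 rose and 0 fell (3.19e-08), with the glutathione peroxidase GPX2 at 3.18 ± 0.12 and GCLM at 1.88 ± 0.06. SLC7A11 rose by 1.89 ± 0.10, although its dimmer probe gave -0.12. In the heme and iron list 10 of 13 rose and 1 fell (2.68e-06), FTL by 2.44 ± 0.05 and HMOX1 by 1.33 ± 0.12. In the NADPH and pentose phosphate list 9 of 14 rose and 1 fell (0.000145), malic enzyme ME1 by 1.08 and transketolase TKT by 1.04. In the thioredoxin list 8 of 13 rose and 1 fell (0.00156), TXNRD1 by 2.86 ± 0.08 and SRXN1 by 2.01 ± 0.07, with TXNIP, an inhibitor of thioredoxin, at -0.73. AhR battery genes rose in 4 of 7 cases and 1 fell (0.00167), NQO1 by 2.73 ± 0.10, and ABC efflux transporters in 4 of 8 with 0 down (0.00372), ABCC2 by 1.98. Of the AhR genes that rose, NQO1, ALDH3A1 and UGT1A6 also stand in the quinone list, so the AhR call is not separate from the quinone call. These 7 calls held with an estimated correlation (adjusted p = 0.000814, 0.000814, 0.00135, 0.00511, 0.0433, 0.043 and 0.0302).

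Proteasome subunits rose in 20 of 31 cases and 1 fell (adjusted p = 0.0021, camera; adjusted p = 0.358 with an estimated correlation), by small amounts such as 0.39 for PSMA3 and 0.26 for PSMA1, while PSMD7 fell by 0.77. Of 19 p53 targets 10 rose and 1 fell (0.00372; adjusted p = 0.0659 with an estimated correlation), with the antiproliferative BTG2 at 1.28 and CDKN1A at 0.90. Cholesterol synthesis genes rose in 14 of 23 cases and 5 fell (0.0408; adjusted p = 0.351 with an estimated correlation), with the sterol sensor partner INSIG1 at 1.01 and squalene epoxidase SQLE at -1.23. That call ended without KEAP1 siRNA array 1 (adjusted p = 0.0691, camera) or 2 (0.0606), without NTC array 2 (0.0532) or 4 (0.0688), and under 5 further settings, with adjusted p from 0.00285 to 0.429 over the camera alternatives.

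Against NTC siRNA, the basal epithelial and mesenchymal lists fell. Both lists stood higher with NTC siRNA than with vehicle, by medians of 1.553 and 0.735, as the comparison of the controls below sets out. Basal epithelial genes fell in 8 of 14 cases and 0 rose (adjusted p = 7.85e-05, camera; adjusted p = 0.0623 with an estimated correlation), with keratin KRT6A at -0.72 and the basal transcription factor TP63 at -0.55. Of 13 mesenchymal genes 4 fell and 0 rose (0.00372; adjusted p = 0.0302 with an estimated correlation): fibronectin FN1 at -2.23 ± 0.10, the actin-binding protein TAGLN at -1.29, SNAI2 at -0.90 and TWIST1 at -0.67. Immediate early genes fell in 11 of 21 cases and 6 rose (0.0339; adjusted p = 0.208 with an estimated correlation), with the growth factor AREG at -1.36, the phosphatase DUSP1 at -1.22 and the growth factor HBEGF at 1.14. That call ended without NTC array 1 (adjusted p = 0.0701, camera), with median centring (0.0523) and with the lowest probe per gene (0.0576), with adjusted p from 0.0206 to 0.208 over the camera alternatives.

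The other lists were not called with KEAP1 siRNA. Counts up and down were 6 and 6 of 29 for DNA replication genes (adjusted p = 0.956, camera), 5 and 3 of 26 for mitosis (0.825), 0 and 0 of 17 for histones (0.786) and 7 and 3 of 23 for ATF4 and amino acid genes (0.606). They were 4 and 2 of 13 for luminal epithelial genes (0.442), where FOXA1 rose by 1.28, and 5 and 3 of 18 for keratinocyte differentiation (0.442). They were 7 and 3 of 20 for heat shock (0.37), 1 and 7 of 19 for the unfolded protein response (0.302), 5 and 6 of 17 for NF-kB and cytokines (0.211), 5 and 1 of 12 for fatty acid synthesis (0.108) and 9 and 3 of 24 for interferon response (0.0877). They were 0 and 4 of 12 for metallothionein (0.0702) and 1 and 0 of 6 for blood and endothelial markers (0.89). Median, mean and test differed in sign for DNA replication (-0.02, 0.03, up), the unfolded protein response (0.02, -0.04, down) and the blood and endothelial markers (-0.02, 0.11, down). Adjusted over the list alone, counts up rose by 1 for thioredoxin, heme, NADPH, heat shock, p53, NF-kB, interferon, fatty acid, AhR and immediate early lists, by 2 for proteasome and by 3 for the unfolded protein response, counts down by 1 for NF-kB and basal lists, and the others were the same.

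Within slides 3 and 4, with 2 arrays per group, 3997 and 3506 genes changed (limma), the changes correlated at r = 0.769 across genes, and KEAP1 changed by -2.46 and -2.42. With the slide as a block 6235 genes changed, and KEAP1 again by -2.44.

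**Figure D2:**
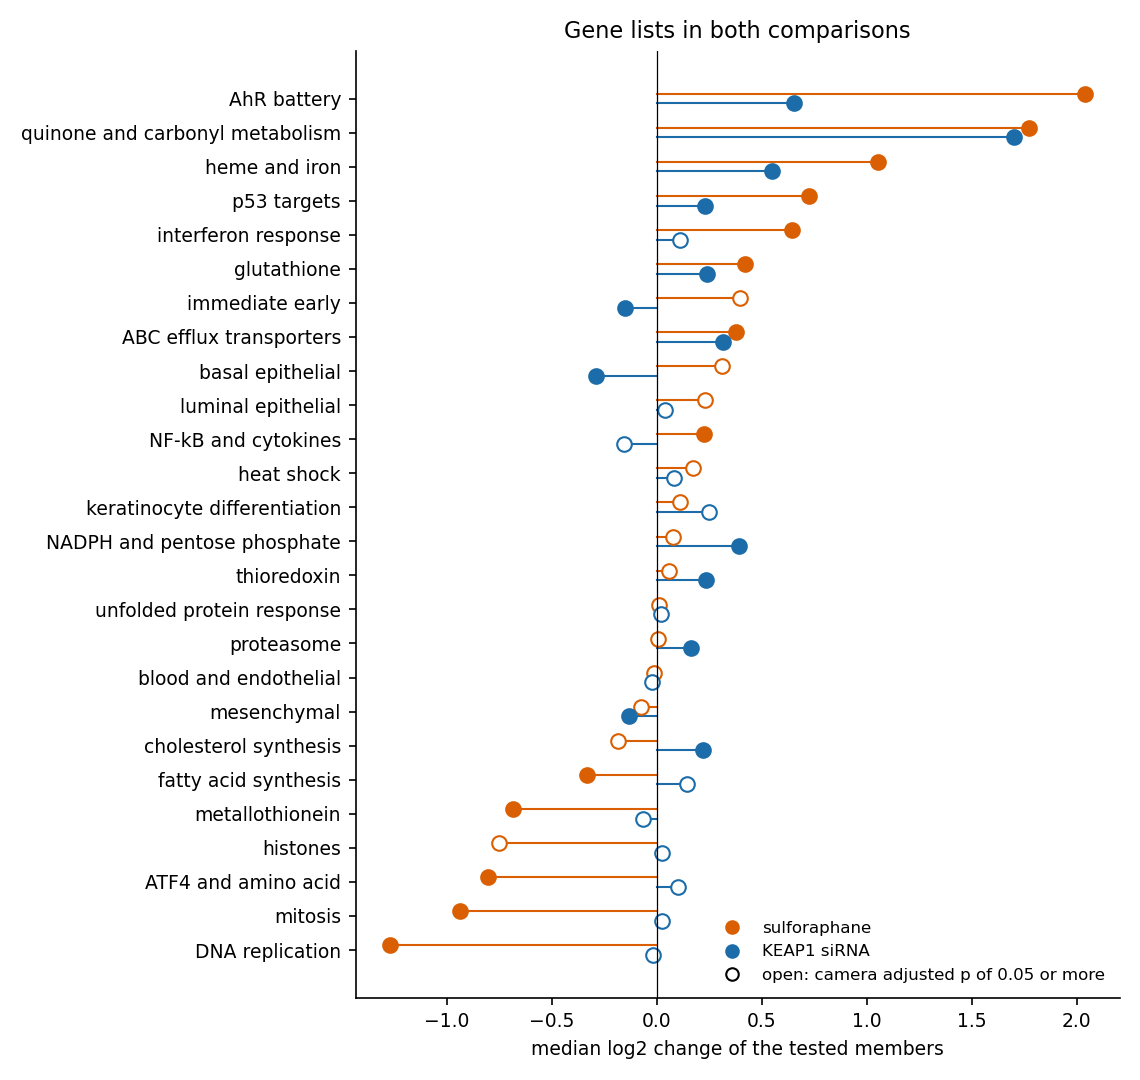
Median log2 change of the 26 gene lists with sulforaphane (against vehicle) and KEAP1 siRNA (against NTC siRNA); filled points are lists called by camera at an adjusted p under 0.05. The quinone and carbonyl metabolism list has medians of 1.77 and 1.70, while DNA replication has -1.27 with sulforaphane and -0.02 with KEAP1 siRNA.

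The third comparison set the pair of responses side by side, asking how far a KEAP1-modifying compound and loss of KEAP1 share changed transcripts. Treated cells of both experiments grew in heavy medium, and their arrays lay at the same slide positions. An effect of medium or position would therefore also appear as a change shared by both responses. Among genes with a symbol, AKR1B10, AKR1C1, AKR1C3 and UGT1A6 had the largest fitted rises common to both, and CYP4F11, also higher in both, is known only by its bounds. CXCL14 fell by 2.08 ± 0.21 with sulforaphane beside the bound given for KEAP1 siRNA, and TDRD10, a Tudor domain protein, fell by 1.23 ± 0.21 and by 1.25 ± 0.21. SLCO2A1, a prostaglandin transporter, dropped by 1.70 ± 0.34 with sulforaphane and was at least 1.81-fold lower with KEAP1 siRNA (adjusted p = 0.00115, limma), a call lost with normexp background correction (adjusted p = 0.0856; 0.000293 to 0.0856 over all alternatives). APCDD1, a Wnt inhibitor, fell by 1.35 ± 0.17 with KEAP1 siRNA and was at least 1.19-fold lower with sulforaphane (8.28e-08, limma), which normexp correction ended (adjusted p = 0.274; 8.03e-09 to 0.274 over all alternatives). SEMA3A, a secreted guidance protein, was at least 1.61-fold lower with sulforaphane (1.38e-08, limma) and below background in both siRNA groups. Its KEAP1 siRNA call (adjusted p = 0.000164, limma) ended without vehicle array 3 (0.2), with no filter on dim probes (0.345) and with normexp correction (0.312), with adjusted p from 9.81e-07 to 0.345 over all alternatives. Vehicle arrays do not enter this comparison. Without vehicle array 3, as with no filter, the change was -0.406, that of another SEMA3A probe that the changed filter let in.

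Genes that rose in both responses numbered 1591 where independence gives 1088.8 (Fisher's exact test, odds ratio 2.18, p = 2.53e-88), and genes that fell in both 989 against 853.3 (1.31, p = 1.06e-09). By the same exact test, 918 rose with sulforaphane and fell with KEAP1 siRNA against 756.3 (1.41, p = 7.54e-14), and 1195 did the reverse against 1228.4 (0.95, p = 0.194). At 2-fold or more, again by Fisher's exact test, 123 genes rose in both against 13.8 (21.61, p = 4.19e-90) and 25 fell in both against 13.2 (2.02, p = 0.00234). Fisher's test takes genes as independent units, which they are not, and both responses use the same estimate of each gene's spread. These p values are therefore descriptive. Of the 50 largest rises in each response 24 were shared, and of the 50 largest falls 0, where chance gives 0.14. Across all 17530 genes, which are not independent replicates, the changes correlated with r = 0.174 (Spearman's rho 0.078), and across 4693 genes changed in both with r = 0.294 (rho 0.157). With median centring of the arrays, 50.7% of the genes changed the same way in both were higher, against 61.7%. Blocking by slide gave 2597 genes changed the same way in both, beside 2580.

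**Figure D3:**
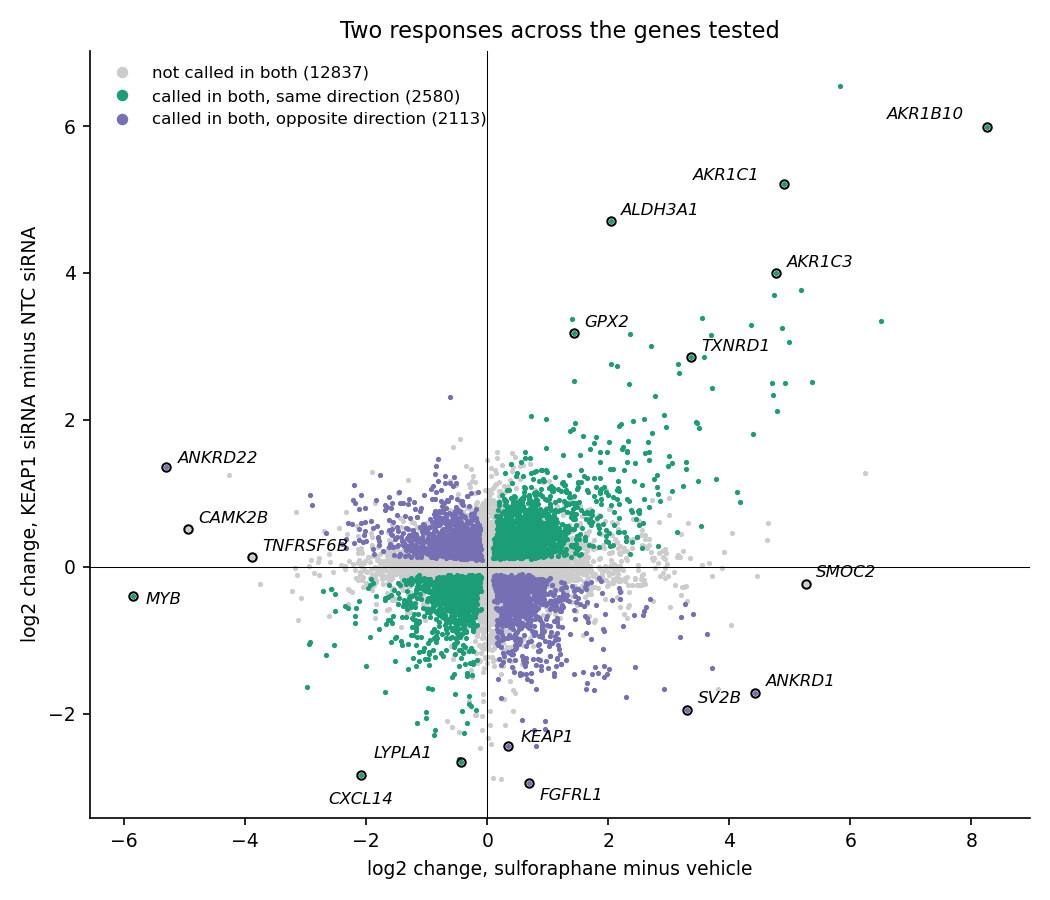
Log2 change with sulforaphane (horizontal axis) against log2 change with KEAP1 siRNA (vertical axis), 1 point per gene and 17530 genes. Colours mark 2580 genes changed the same way in both, 2113 changed in opposite directions and 12837 not called in both, and AKR1B10 lies at 8.26 and 5.99.

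The responses differed for 9767 genes (55.7%, limma test of the difference), with the sulforaphane change higher for 4321 and lower for 5446. TNFRSF6B changed by -3.88 ± 0.08 with sulforaphane and 0.13 with KEAP1 siRNA (difference -4.01 ± 0.11, adjusted p = 5.36e-12, limma), and CAMK2B by -4.95 and 0.52 (difference -5.46 ± 0.38, 2.53e-08). MYB (-0.40 with KEAP1 siRNA), ANKRD22 (1.36) and CA9 (below background with NTC siRNA) were also lower in the sulforaphane response (difference tests, adjusted p = 1.24e-11, 1.26e-09 and 5.45e-06, limma). ANKRD1, a muscle ankyrin protein induced by stress, was at least 5.73-fold higher with sulforaphane and at least 1.37-fold lower with KEAP1 siRNA (difference, 1.97e-07). SV2B, a synaptic vesicle protein, was at least 7.95-fold higher and at least 1.79-fold lower (9.35e-09), and DNAI4, an axonemal dynein protein, at least 8.72-fold higher and at least 1.53-fold lower (1.87e-07). ANKRD1, SV2B and DNAI4 were also higher with NTC siRNA than with vehicle, at least 1.504-fold, 1.965-fold and 1.673-fold. SMOC2 was well above background with sulforaphane and on 0 arrays of the other groups (9.68e-09), and FER1L4, a transcribed pseudogene of the ferlin family, changed by 4.03 ± 0.75 with sulforaphane (difference 4.82, 0.00131), with 1 of 4 arrays above background in each of the other groups. NTC array 4 stood at -0.288 for FER1L4 (others -5.067 to -3.955), and without it the difference was 3.80 (adjusted p = 3.87e-05, limma).

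At the preset correlation the cell cycle lists had the smallest p for the difference. DNA replication genes were lower in the sulforaphane response for 29 of 29 (adjusted p = 2.64e-14, camera; adjusted p = 0.0372 with an estimated correlation), POLA1 by -2.20 ± 0.07 and the ribonucleotide reductase subunit RRM2 by -1.91, and mitosis genes for 24 of 26 (4.3e-10; adjusted p = 0.0924 with an estimated correlation), MKI67 by -1.87. The heme and iron list was higher in the sulforaphane response, 7 of 13 up and 1 down (0.00436; adjusted p = 0.059 with an estimated correlation), HMOX1 by 1.95 ± 0.16. So were p53 targets, 14 of 19 up and 2 down (0.00082; adjusted p = 0.0783 with an estimated correlation), CDKN1A by 1.96, and basal epithelial genes, 7 of 14 up and 1 down (0.00436; adjusted p = 0.177 with an estimated correlation), KRT6A by 1.87 and laminin LAMA3 by 1.52. Interferon response genes were higher for 14 of 24 and lower for 3 (0.00924; adjusted p = 0.159 with an estimated correlation), immediate early genes for 13 of 21 and 3 (0.00968; adjusted p = 0.151 with an estimated correlation), DUSP1 by 2.25, and NF-kB and cytokine genes for 9 of 17 and 3 (0.0155; adjusted p = 0.183 with an estimated correlation), CCL20 by 2.55. ATF4 and amino acid genes were lower for 16 of 23 and higher for 2 (0.00082; adjusted p = 0.151 with an estimated correlation), CHAC1 by -1.72, and fatty acid synthesis genes lower for 9 of 12 and higher for 1 (0.00803; adjusted p = 0.0924 with an estimated correlation), SREBF1 by -1.53. NADPH and pentose phosphate genes were lower for 9 of 14 and higher for 1 (0.042; adjusted p = 0.117 with an estimated correlation), IDH2 by -1.49. That call ended without NTC array 1 (adjusted p = 0.0525, camera) and under 5 further settings, with adjusted p from 0.013 to 0.117 over the camera alternatives.

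The remaining 15 lists were not called for the difference, among them quinone and carbonyl metabolism (8 up, 7 down of 17, adjusted p = 0.439, camera), glutathione (6 and 6 of 21, 0.868), thioredoxin (5 and 7 of 13, 0.868), proteasome (4 and 12 of 31, 0.368), mesenchymal (5 and 2 of 13, 0.165) and cholesterol synthesis (5 and 12 of 23, 0.13). Median, mean and test differed in sign for thioredoxin (-0.18, 0.07, up), the AhR battery (0.14, -0.03, up), luminal (-0.08, -0.06, up) and keratinocyte differentiation genes (-0.28, -0.02, up) and the blood and endothelial markers (-0.01, -0.04, up). Adjusted over the list alone, counts were the same except for immediate early genes (5 down). The slide block gave 9877 genes that differed.

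**Figure D4:**
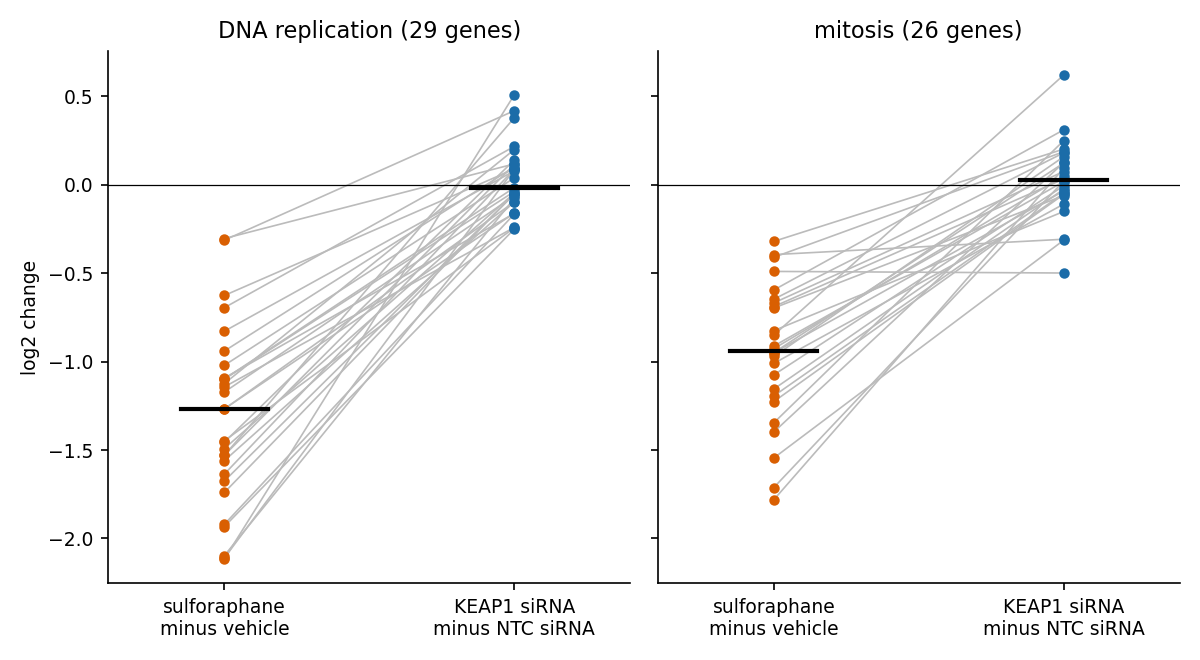
Log2 change of 29 DNA replication and 26 mitosis genes with sulforaphane and with KEAP1 siRNA, 1 point per gene with lines at the medians. The sulforaphane medians are -1.27 and -0.94, against -0.02 and 0.03 with KEAP1 siRNA.

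The last comparison set NTC siRNA against vehicle, the controls of the pair of experiments, which also differ in transfection and in slide. MMP9, a gelatinase, was higher by 5.52 ± 0.10 with NTC siRNA, SPRR2D, a cornified envelope protein, by 5.27 ± 0.16, and the collagenase MMP1 at least 14.4-fold (adjusted p = 7.33e-14, limma). SCG5, a neuroendocrine chaperone, was at least 15.0-fold higher (6.01e-09) and KANK4 at least 7.07-fold (1.64e-14). The ribosomal protein pseudogene RPL23AP71 was lower (-4.64 ± 0.07), and TMEM129, an endoplasmic reticulum ubiquitin ligase, at least 11.95-fold lower (2.78e-10). PRPS1L1, a testis paralog of a nucleotide synthesis enzyme, was at least 11.95-fold lower (3.93e-12), HNRNPCL1 at least 11.1-fold (7.62e-09) and LRATD2 at least 9.06-fold (1.03e-13), with a second LRATD2 probe at -0.99. In limma 11611 genes (66.2%) differed, 5991 higher and 5620 lower, and 2461 by at least 2-fold, 836 higher and 1625 lower; groups did not overlap for 10636 (60.7%), where chance gives 2.9%.

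Basal epithelial genes were higher with NTC siRNA in 11 of 14 cases and lower in 2 (adjusted p = 0.000617, camera; adjusted p = 0.233 with an estimated correlation), with keratins KRT6B at 4.02 ± 0.24 and KRT17 at 2.56 ± 0.08. Mesenchymal genes were higher in 9 of 13 and lower in 2 (0.0256; adjusted p = 0.233 with an estimated correlation), FN1 by 3.31 ± 0.10 and TAGLN by 2.87 ± 0.08. Unfolded protein response genes were higher in 15 of 19 and lower in 3 (0.00555; adjusted p = 0.253 with an estimated correlation), the chaperone CALR by 1.13. Interferon response genes were higher in 15 of 24 and lower in 2 (0.00882; adjusted p = 0.233 with an estimated correlation), IFI27 by 2.14, and mitosis genes in 16 of 26 and 3 (0.048; adjusted p = 0.705 with an estimated correlation), MKI67 by 0.81. ATF4 and amino acid genes were lower in 17 of 23 and higher in 1 (0.000617; adjusted p = 0.233 with an estimated correlation), the serine synthesis enzyme PHGDH by -1.72 and asparagine synthetase ASNS by -1.45. Cholesterol synthesis genes were lower in 15 of 23 and higher in 5 (0.048; adjusted p = 0.474 with an estimated correlation), SQLE by -0.76, and fatty acid synthesis genes in 10 of 12 and 2 (0.048; adjusted p = 0.233 with an estimated correlation), SREBF1 by -1.22.

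The other 18 lists were not called between the controls, including quinone and carbonyl metabolism (3 higher, 11 lower of 17, adjusted p = 0.0632, camera) and keratinocyte differentiation (11 and 4 of 18, 0.126). The median of the keratinocyte list was 0.85, or 0.68 with dim or saturated genes at their bounds, and that of metallothionein 0.17, or 0 at the bounds; in the sulforaphane and knockdown comparisons such a median moved by 0.073 at most. Median, mean and test differed in sign for thioredoxin (-0.06, 0.00, down), heme and iron (-0.01, 0.08, up) and metallothionein (0.17, -0.13, up), and counts adjusted over the list alone were the same except for interferon response (16 higher) and mesenchymal genes (3 lower). With median centring 65.4% of the differing genes were higher, against 51.6%, and the median of all genes was 0.17 against 0.03. No slide held both control groups, so no within-slide value exists; with the slide as a random block 11527 genes differed, and the slide and the group cannot be told apart.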

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

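The tests of pseudogene medians, GC intervals, names without a match, seed words, array position, slides, array scaling and knockdown medians in this part were chosen only after the result was seen.

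For the genes whose values the text gives, the largest changes under the naming rule and 5 array measures, 37 of 559 groups of 4 values held 1 array far from the other 3 by Dixon's criterion, where chance marks about 1 in 20 groups (27.9). List members that the text does not name were not examined in this way, and 5 groups with saturated arrays were left out. All levels here are scaled log2 intensities. MYB stood at 0.208 in vehicle array 4 (others 0.087 to 0.107) and at -5.287 in sulforaphane array 3 (others -5.921 to -5.829). Vehicle array 1 was high for ANKRD1 at -5.499 (others -6.84 to -6.614) and SLCO2A1 at -1.855 (others -3.255 to -3.063). The same array had the highest 75th percentile of intensity in its group, 329.5 (others 259.4 to 270.8), and the most saturated spots, 158 (others 115 to 121). HNRNPCL1 was low in vehicle array 3 at -0.984 (others -0.761 to -0.725), and MYL9 in vehicle array 4 at -3.594 (others -3.308 to -3.285), an array that was high for PDPN at 1.394 (others 1.235 to 1.25). In NTC array 2, SFT2D1 stood at 4.128 (others 4.471 to 4.537), PDPN at 2.432 (others 2.314 to 2.322) and CYP4F2 at -2.512 (others -2.017 to -1.943). For NTC array 4 the values were -2.238 for UGT1A6 (others -2.173 to -2.165), 1.173 for TNFRSF6B (others 1.083 to 1.084) and -3.71 for TDRD10 (others -3.315 to -3.237). KEAP1 siRNA array 1 was low for OSGIN1 at 0.363 (others 0.633 to 0.67) and for CA9 at -5.277 (others -4.02 to -3.852), KEAP1 siRNA array 2 was low for F2RL2 at -4.168 (others -3.925 to -3.884), and KEAP1 siRNA array 4 was high for SEMA3A at -5.513 (others -6.512 to -6.423).

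Among the gene list members named in the text, vehicle array 1 was high for AURKB at -0.098 (others -0.55 to -0.502). Vehicle array 2 was low for SCD at 4.713 (others 4.785 to 4.799), and vehicle array 4 high for RRM2 at 2.999 (others 2.672 to 2.725) and low for TXNIP at 3.774 (others 4.0 to 4.042). With sulforaphane, TXNIP stood at 4.146 in array 1 (others 4.443 to 4.498), PSMD7 at 5.225 in array 2 (others 5.132 to 5.147) and HMOX1 at 1.372 in array 4 (others 1.541 to 1.564). NTC array 1 was low for TP63 at 3.337 (others 3.428 to 3.446). NTC array 2 was low for GCLM at 0.911 (others 1.171 to 1.207) and DUSP1 at 2.048 (others 2.285 to 2.313), and high for CDKN1A at 2.823 (others 2.502 to 2.525), CALR at 5.477 (others 5.345 to 5.367) and PGLS at 2.807 (others 2.697 to 2.713). KEAP1 siRNA array 1 was low for CRYAB at -0.313 (others -0.073 to -0.051) and TP53INP1 at 0.134 (others 0.238 to 0.251), and array 2 for TXNRD1 at 0.784 (others 0.848 to 0.855) and SRXN1 at 4.598 (others 4.7 to 4.719). CBS, in the ATF4 and amino acid list, stood at -7.184 in sulforaphane array 2 (others -2.994 to -2.872).

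DNA replication and mitosis genes fell with sulforaphane in 55 of 55 cases. Array scaling as the whole cause is argued against by a median that was -0.82 at its highest over 4 scalings, and the labelled medium by the knockdown cells, which shared it and had a median of 0.02 over the same genes. A smaller share of cycling cells after sulforaphane is a candidate explanation: 46 other cell cycle genes, listed without looking at their values, had a median of -0.92, with 44 falling and 0 rising (limma). Lower transcription of these genes in cells that kept cycling would give like values and was not tested, and cells were not counted. The reading stays a hypothesis, found and tested on the same arrays.

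With KEAP1 siRNA 259 genes fell at least 2-fold. Array position or labelled medium, shared by treated arrays of both experiments, is argued against by a median sulforaphane change of 0.17 for these genes, and a difference between slides by 253 of 262 genes picked by falls in slide 3 values (96.6%) being lower on slide 4 and 243 of 250 picked in slide 4 values being lower on slide 3. Seed matches of the siRNA, whose sequence is not given, may lower transcripts other than KEAP1, but the most enriched word in the probe sequences was found in 7 genes against 0.99 by chance, and a share of 0.339 of random gene sets had a word as enriched. A wider set of 546 genes, falling by 0.7 log2 units or more and looked at first, had a word in 10 genes against 1.37, with a share of 0.016. Probes cover 60 bases of a transcript, so off-target silencing stays open, as does a response to the loss of KEAP1 itself.

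Many probes were dimmer with NTC siRNA than with vehicle: 22.3% of 292 pseudogenes and 22.2% of 4537 names without a match were at least 2-fold lower, against 4.3% of 12471 protein-coding genes. Cross-hybridization that differed between the experiments may contribute, since probes of 1 gene spread 2.04 times as widely as in the sulforaphane comparison, but the pseudogene median lay only -0.28 from that of protein-coding genes. GC content of the probes, with a rho of 0.243, is argued against as the cause of the excess by gaps of -0.41 for pseudogenes and -0.3 for names without a match within bins of GC content, with 95% intervals of -0.53 to -0.24 and -0.32 to -0.27, a rule set after the values were seen because the bound of 0.5 written beforehand lay beyond the gap of -0.28 without bins and was not reached. Transfection with siRNA is the biological alternative, and 0 slides hold both control groups. Cross-hybridization and transfection cannot be told apart, because slide, experiment and transfection coincide.

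Other splits of the same arrays into groups of 4 were set beside the real one. For sulforaphane against vehicle 1 of 35 splits, the real one, gave as many changed genes (11175, highest other 4). So did 1 of 35 for KEAP1 siRNA (6160, highest other 38) and 1 of 35 for the controls (11611, highest other 4). That share, 2.9%, is the smallest that 35 splits can give. Mixed groups also spread more widely, so the gap to the other splits does not measure chance. For the controls the slide and the group coincide, so the splits cannot tell them apart. The highest other split of the siRNA arrays followed the slides, within which 3997 and 3506 genes changed, and the slide block gave 6235. Of 100 splits of both experiments, 1, the real one, reached the real value for the difference of the responses (9767, highest other 8082). The highest other split kept the real sulforaphane groups. The same held for genes changed the same way in both (2580, highest other 1). Splits that kept neither real grouping gave at most 1 and 0 genes, since mixing treated and control arrays weakens both responses and widens the spread within groups. These splits show only that genes respond, and cannot tell whether the responses differ or are shared beyond chance. For the correlation 1 of 100 splits reached the real value (0.174, highest other 0.171). In that other split 3 of 4 treated arrays of each experiment stayed together, so part of both responses remained. Its value also lies within the 0.165 to 0.178 seen with 1 array left out. Such splits give no reference for chance, which is not firmly excluded for the correlation. With KEAP1 siRNA 1 of 35 splits gave as many called gene lists (13, highest other 12), and leaving out 1 array gave 12 to 14 lists. With sulforaphane 4 of 35 splits did (13, highest other 15), and for the difference 15 of 100 (11, highest other 15). In the highest other split for the difference, 3 of 4 sulforaphane arrays stayed together. Camera compares genes with each other, so a response weakened by mixing can still give calls. The splits therefore cannot decide whether the numbers of called lists exceed chance.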

How the results depend on the processing

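The alternative with named genes only was chosen after seeing the data; the others were planned. Leaving out each array in turn gave 10708 to 11474 genes changed with sulforaphane, 5468 to 6185 with KEAP1 siRNA, 9426 to 9867 for the difference, 11128 to 11746 between the controls and 2276 to 2580 changed the same way in both. The correlation of the responses ran from 0.165 to 0.178, the KEAP1 change from -2.469 to -2.404 (-1.709 with normexp background and quantile scaling), and called lists from 13 to 16, 12 to 14 and 10 to 13 for sulforaphane, KEAP1 siRNA and the difference. Named genes only gave 8249, 5028, 7357, 8254 and 2156 genes, since fewer genes were tested. The deposited series values equalled the main values and moved nothing, and the scan was not run as a block because it does not differ from the slide. Probes near background limit what can be seen: 1127 of 17530 tested genes were dim in at least 1 group.

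With thresholds of 1.5-fold and 2-fold fewer genes passed by construction: 4834 and 2003 with sulforaphane, 1471 and 476 with KEAP1 siRNA, 5256 and 2398 for the difference, 5168 and 2461 between the controls, and 441 and 148 the same way in both, where an adjusted p under 0.01 left 1684. The estimated correlation in camera left 5, 8 and 1 lists for sulforaphane, KEAP1 siRNA and the difference, and fry, which does not compare a list with other genes, called 23, 20 and 22. The correlation of the responses was 0.157 with normexp background and quantile scaling, 0.153 with no filter on dim probes and 0.136 for probes well above background on all 16 arrays; the cause was not tested. Without the filter the median of all genes was -0.153 with sulforaphane and 0.153 between the controls.

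Replicate numbers were not taken to pair arrays: deviations of treated and control arrays with the same number correlated at 0.073 to 0.21, above 0.1 for 6 of 8 pairs and not for all, and 6 of 8 arrays correlated best with their own number. Mean correlations were lower for other numbers on the same slide (0.065) and on the other slide (-0.106), so pairing is not excluded. With a replicate block 11301, 6004, 9846 and 11858 genes passed for sulforaphane, KEAP1 siRNA, the difference and the controls, and 2497 the same way in both; 10891, 5585, 9390 and 11342 of the main calls were kept in the same direction. The slide block gave 11225, 6235, 9877, 11527 and 2597, and kept 11016, 5950, 9609 and 11523. The replicate block ended the call of the NADPH and pentose phosphate list for the difference (adjusted p = 0.0681, camera) and brought histones past the threshold with sulforaphane (0.0337) and for the difference (0.0292). The slide block brought immediate early genes (0.0459) and histones (0.0449) past it with sulforaphane, and histones for the difference (0.045).

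Among values of named genes, 7771 of 7824 with 1 array left out and 6934 of 7002 under other settings kept their direction and their side of the threshold, as did 1218 of 1248 and 1145 of 1248 for the lists. Part of this agreement was fixed in advance. Arrays of the other experiment enter a treatment comparison only through the spread and the choice of probe, and the deposited series values equalled the main ones. Direction reversed for the following log2 values, and the cause was not tested. Another probe of the same gene gave, with the lowest probe, -0.721 for PSMD12, -0.299 for SC5D and 1.373 for H2BC21 with sulforaphane, -0.12 for SLC7A11 with KEAP1 siRNA, and 0.518 for ABCC5 and 1.136 for H2BC21 in the difference. Between the controls the lowest probe gave 0.32 for SLC7A11, -3.541 for GSTT2, 0.111 for PRDX2, -0.279 for ALDH1A3, 0.253 for ABCB6, -0.409 for PGLS and -0.307 for PSMD12, the mean of the probes gave -1.424 for GSTT2, and normexp gave 0.249 for ABCB6. Values not past the threshold also turned: NFE2L2 with sulforaphane, to -0.009 with array weights and from -0.027 to 0.1 with 1 array left out, and CYP4F3 with KEAP1 siRNA, below background in both siRNA groups and so without a direction to read, at 0.112 with quantile scaling, 0.011 with array weights and -0.097 to 0.09 with 1 array left out. CYP4F30P ran from -0.173 to 0.044 with sulforaphane and from -0.119 to 0.064 with KEAP1 siRNA when 1 array was left out.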

Other observations

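The genes in this part were chosen after their values were seen, as were the Fisher's exact tests at a 2-fold threshold that lead to some of them, and no explanation is offered for them. Beyond the largest changes, other members of the CYP4F family, cytochrome P450 enzymes that hydroxylate fatty acids and eicosanoids at the omega end, rose in both responses. CYP4F2 rose by 3.16 ± 0.11 with sulforaphane and 2.64 ± 0.11 with KEAP1 siRNA, and CYP4F8 by 2.95 ± 0.08 and 1.91 ± 0.08 (SE, n = 4 arrays per group). CYP4F3 was at least 3.76-fold higher with sulforaphane (adjusted p = 4.2e-11, limma) and below background in both siRNA groups. The pseudogene CYP4F30P differed by -0.06 and -0.05 (adjusted p = 0.725 and 0.809, limma). SPANX genes, which are normally expressed in testis, were also higher: SPANXA1 at least 3.51-fold with KEAP1 siRNA (4.3e-06, limma), beside at least 18.1-fold with sulforaphane, and SPANXB1 with sulforaphane (5.28e-11, well above background on 4 of 4 arrays against 0 of 4). Members of either family share sequence, so their probes are not independent measurements of each gene.

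A set of 36 genes was at least 2-fold higher with sulforaphane and at least 2-fold lower with KEAP1 siRNA, where independence gives 16.4 (Fisher's exact test, p = 8.13e-06), and 4 genes, ANKRD22, AQP3, CYB5R2 and EYA1, did the reverse against 11 (exact p = 0.0277). Genes are not independent units, so these p values are descriptive. The 4 of the 36 with the largest smaller change among those measured above background on all 16 arrays were CDKN1C, ATP6V0A4, RGS2 and MYL9. CDKN1C, a cyclin-dependent kinase inhibitor, changed by 1.65 ± 0.10 and -1.58 ± 0.10, and ATP6V0A4, a subunit of the proton pump, by 1.98 ± 0.10 and -1.46 ± 0.10. RGS2, a regulator of G protein signalling, changed by 1.73 ± 0.07 and -1.46 ± 0.07, and MYL9, a myosin light chain of contractile cells, by 1.83 ± 0.08 and -1.45 ± 0.08. The control levels differed too: NTC siRNA minus vehicle was 1.45 for ATP6V0A4, 1.26 for RGS2, 2.96 for MYL9 and -1.11 for CDKN1C. The rises and falls of these genes therefore start from different levels.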
